A study of Homo sapiens with 3 samples.

How the data were processed

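Total RNA of HCC827 cells and of 2 resistant clones was labelled with biotin and hybridised to Illumina HumanHT-12 v3 BeadChips, per the labels' protocols. Groups were taken from the labels, which give 1 parental array and 2 resistant arrays. The deposited non-normalized table holds a linear intensity for each of 48803 probes and 3 arrays, with no detection p-value, bead number, bead error or control probe, and the software that summarised the beads is not given in the sources used here. The intensity values had not been background-subtracted: the lowest were 38.4, 35.9 and 37.9 in the parental array, clone 1 and clone 2. The second deposited table, the authors' processed values, is also a linear intensity. Its columns have medians of 59.6, 59.7 and 59.7, share one distribution to within 0.352 signal units and correlate with the first table on the log2 scale at r of 0.99997, 0.999995 and 0.99995, so that its scale is that of quantile-normalized intensity without a log, without centring and with 1 colour per array. How the authors computed it is not given in the sources used here.

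The planned normalization used negative controls inferred from detection p-values, which the file does not hold. In its place, background was corrected with normexp without controls (limma backgroundCorrect, offset 16), followed by log2 and quantile normalization between the arrays. Detection was estimated from each array's own dim probes: the mode of log2 signal was taken as background, the spread of the values below it as its SD, and a probe exceeded background where its one-sided p was under 0.01. The resulting thresholds were signals of 71.0, 66.3 and 71.5, passed by 16560, 16761 and 16241 probes. Among 573 probes of olfactory, taste, vomeronasal receptor and keratin-associated protein genes, expected to be silent, 3.66%, 3.84% and 3.84% passed, above the nominal 1%, so some dim genes called detected are not.

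Probes were named from the platform annotation given for this table and their symbols updated by Entrez ID through the RefSeq gene table of GRCh38.p14, which was also used for the order of neighbouring genes. Of the probes, 28098 had 1 gene, 13 had several and 20692 were not listed; 28059 symbols were matched to the RefSeq table and 39 kept the annotation's name. A named probe entered if it exceeded background on at least 1 array, which left 15545 probes, and a gene was represented by its brightest probe, which left 11747 genes. Of 3056 genes with a second entering probe, 202 were called, and in 197 of those the second probe had the same direction, in 139 with at least a 2-fold difference.

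Resistant clones were compared with parental cells by limma (version 3.58.1 in R 4.3.3; lmFit and eBayes, matrixStats 1.5.0), with Benjamini-Hochberg adjustment over 11747 genes and a threshold of 0.05. The test has 1 residual degree of freedom and a prior of 4.04, and takes the spread from the clones alone; nothing in the labels says that parental cells vary as they do. The p-values set a difference against the spread between these 2 clones, pulled toward the spread over all genes, and treat the clones as independent. Genes at least 2-fold higher or lower were counted by size in each clone, in both, and between the clones. A gene whose probe was below background on each array of a group is given as at least N-fold, from the bright group's mean against the mean over the dim group's arrays of the lowest normalized signal that exceeded background there.

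A total of 27 gene lists with 608 members, 566 of them named on the array, were fixed before the data were examined: ERBB receptors and ligands, other receptor kinases and ligands, ERK pathway output, SRC family and other dasatinib targets, focal adhesion adaptors, integrins, epithelial, mesenchymal, TGF-beta, YAP and TEAD, cell cycle, CDK inhibitor and p53, BCL2 family, NRF2, ALDH and transporter, interferon, MHC, NF-kB, lung, squamous, neuroendocrine, leukocyte, endothelial, glycolysis, sterol, stress and housekeeping genes. B2M and SESN2 stand in a pair of lists each. The median of each list was set against 10000 random lists of equal size drawn from the same 20 expression bins, and a percentile under 2.5 or over 97.5 was taken as standing apart; this describes these arrays and is no test between conditions.

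The genes to name were fixed by rule before the data were examined: EGFR, MET, AXL and SRC; the 12 highest and 12 lowest in both clones by the smaller of the clones' differences; up to 4 members of each list at least 2-fold off in both clones and up to 2 that differed by 2-fold between the clones; the brightest member under 2-fold; and the 6 genes farthest apart between the clones in each direction. Provisional gene symbols were left out of the rankings. Neighbouring genes were named after their values had been seen.

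Agreement of the clones was set against 100 simulations of unchanged arrays whose noise was drawn from the differences between the clones, divided by the square root of their number, within expression bins, since bead errors were not given. The fit was tested on simulated data with the noise of these arrays for 11747 genes, of which 200 had known changes. These 200 were drawn from brighter genes alone, so the rates of recovery do not cover genes near background. Limma recovered 0% of 50 genes changed by a log2 of 1, 36% at 2, 94% at 3 and 100% at 4, and the rule of 2-fold in both clones recovered 30%, 94%, 100% and 100%. Of 11547 unchanged genes 28 were called by limma and 163 passed the 2-fold rule.

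Neighbouring genes were scanned after the data were seen with running medians of 7 genes over 11735 placed genes, against 1000 shuffles of the gene order. Alternatives were no background correction, median scaling, the authors' values, a filter on all 3 arrays, no filter, the mean of a gene's probes, a trend in eBayes, size rules of 1.5-fold and 3-fold, and leaving out each clone. An offset of 50, a filter at the 99th percentile of the silent gene families and a limma test against 2-fold were added after the data had been seen. The chip as a block was not run because the deposited columns name no chip. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probes with several genes or none listed were left out of the comparisons.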

Results

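Gene expression was measured on Illumina HumanHT-12 v3 arrays in HCC827 cells, a human lung adenocarcinoma line whose growth depends on a mutant EGFR, and in 2 sublines resistant to BIBW2992 (afatinib), an irreversible inhibitor of EGFR and ERBB2. The resistant cells were grown out under rising drug concentrations that reached 2 µM over 3 to 4 months, and the sublines were set up from clones. There was 1 array of parental cells and 1 array of each clone, called clone 1 and clone 2 here, with no repeat array of any of them. The labels do not say whether drug was in the medium when RNA was taken. No array was labelled as an unselected clone or as parental cells matched for time in culture. A difference from parental cells therefore covers selection, cloning, time in culture and any drug still present, which cannot be told apart. The series title names dasatinib, an inhibitor of SRC family, ABL and several other kinases, against the resistant cells, and no array was labelled as treated with it. Median signals were 60.4 on the parental array, 57.3 on the array of clone 1 and 61.2 on that of clone 2, and 33.9%, 34.3% and 33.3% of the 48803 probes exceeded background. After filtering, 11747 genes had a value on each array, and the number of arrays limits the precision of all that follows.

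The first comparison asked what the resistant clones had in common against parental cells. Genes below background in parental cells and abundant in both clones included ALDH1A1, a retinaldehyde dehydrogenase, at least 204-fold higher, and CRP, an acute-phase protein, at least 158-fold higher. CA2, a carbonic anhydrase, was at least 89.6-fold higher on its brightest probe and higher by a log2 difference of 5.66 on its other probe, which exceeded background in parental cells. At the other end, MAL2, a protein of apical transport in polarized epithelia, was at least 107-fold lower, CDH3, which encodes P-cadherin, at least 98.7-fold lower, and CEACAM6, a cell-surface adhesion protein, at least 55.3-fold lower. Limma called 681 of the 11747 genes at a Benjamini-Hochberg adjusted p under 0.05, of which 315 rose and 366 fell. By size alone, 557 genes were at least 2-fold higher in both clones and 628 at least 2-fold lower, 10.1% of the genes together, and 3 genes were at least 2-fold off in opposite directions. Of the higher genes 179 were below background in parental cells, and for 146 of these the bound set by background was itself at least 2-fold; of the lower genes 191 were below background in both clones, and the bound reached 2-fold for 137. All 681 called genes were among those 2-fold off in both clones, which a test on the spread between the clones favours.

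Each p-value rests on the spread between the clones alone, with 1 residual degree of freedom. That spread is pulled toward a prior drawn from all genes, which counts for 4.04 degrees of freedom. The test assumes that parental cells vary as the clones do and that the clones are independent. The labels do not say whether the clones arose from separate cells. In simulated arrays of unchanged genes that carried the noise of these clones and shared 1 parental array, a median of 70 genes came out at least 2-fold higher in both clones and 68 lower, with at most 86 in either direction. Where known changes were simulated, false calls were a larger share of the limma calls than the threshold allows, so calls near the threshold are less certain.

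Among the 12 genes highest in both clones by the smaller of their differences, ALDH1A1, TNFAIP6, CRP, IGFBP7, ERVW-1, TENM3, CLDN2, SEMA6A and PPP2R2C were below background in parental cells, as was the brightest probe of CA2, and their increases are lower bounds. IGFBP7, a secreted protein that binds insulin-like growth factors, rose at least 73-fold (limma adjusted p = 0.00265), CLDN2, a pore-forming claudin, at least 68.2-fold (adjusted p = 0.0116), and TENM3, a transmembrane teneurin, at least 58.5-fold. ERVW-1, which encodes the fusogenic envelope protein syncytin-1, rose at least 67.4-fold, SEMA6A, a semaphorin, at least 32.7-fold, and PPP2R2C, a regulatory subunit of protein phosphatase 2A, at least 30.9-fold. GLDC, the glycine-cleaving decarboxylase of mitochondria, was measured on all 3 arrays and rose 95.7-fold (log2 6.58, SE 0.33, adjusted p = 0.00330), the top of a log2 range that began at 5.90 over the settings tried. AKR1C2, an aldo-keto reductase, rose 255-fold (adjusted p = 0.00536), although its probe can pick up close relatives of the same family. Its second probe differed by 0.89 on the log2 scale and was above background in clone 1 alone. TNFAIP6, a hyaluronan-binding protein, rose at least 117-fold on its brighter probe. Its second probe differed by -0.0513, but was below background in parental cells and clone 1 and barely above it in clone 2.

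The 12 lowest genes were MAL2, CDH3, ERP27, KRT16P2, CEACAM6, CST6, SGPP2, ADGRF1, IGFBP3, PRODH, RAB25 and PLAAT4. ERP27, a chaperone of the endoplasmic reticulum, fell at least 86.6-fold, CST6, a cysteine protease inhibitor, at least 37-fold, ADGRF1, an adhesion G-protein-coupled receptor, at least 46.6-fold, and RAB25, an epithelial small GTPase, at least 45.4-fold, with both clones below background. IGFBP3, a carrier of insulin-like growth factors, fell at least 74.5-fold in clone 1, where it was below background, and 63.6-fold in clone 2. PRODH, the first enzyme of proline breakdown, fell 56.6-fold in clone 1 and at least 60.4-fold in clone 2, where it was below background. PLAAT4, a phospholipase-like protein, was above background on all 3 arrays and fell 79.3-fold (log2 -6.31, SE 0.50, limma adjusted p = 0.00665). SGPP2, a sphingosine phosphate phosphatase, fell at least 34.9-fold on its brighter probe. Its other probe differed by -0.82, but was barely above background in parental cells and below it in both clones. KRT16P2 is a keratin pseudogene, whose probe may also detect the parent gene KRT16; it fell 100-fold in clone 1 and at least 101-fold in clone 2, where it was below background.

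**Figure D1:**
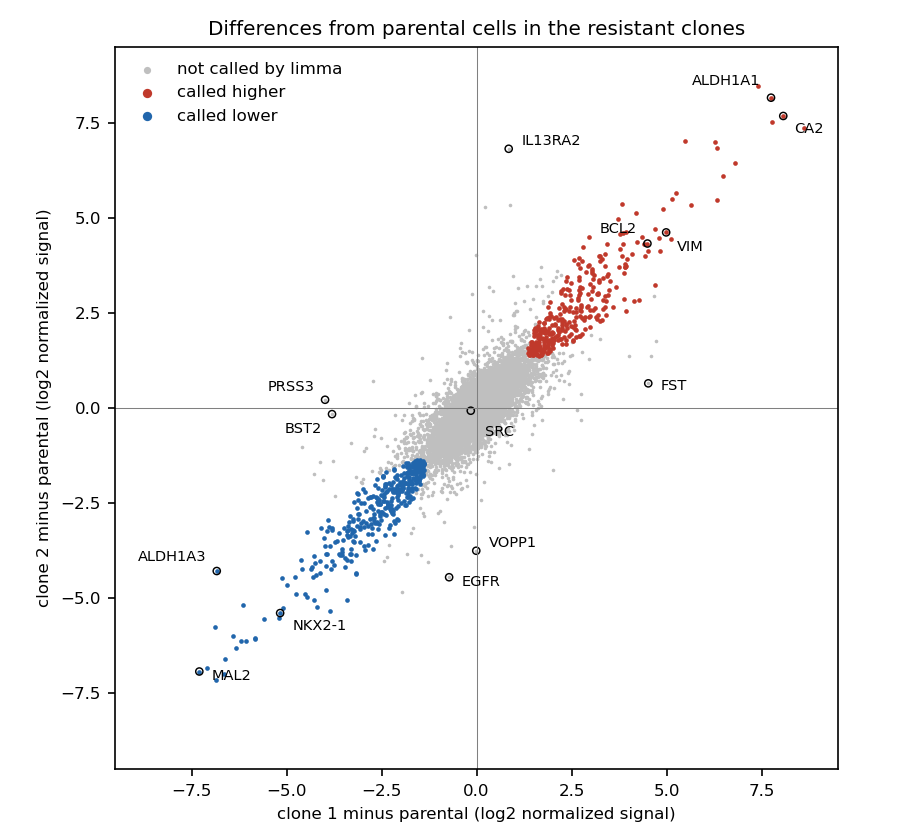
Each point is 1 of 11747 genes, with the log2 difference from parental cells in clone 1 on the horizontal axis and in clone 2 on the vertical axis; red and blue points are the 315 genes that limma called higher and the 366 called lower, and circles mark labelled genes. Called genes lie along the diagonal, as a test with its spread from the clones requires, while EGFR and VOPP1 lie far below it and IL13RA2 far above it.

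The clones resembled each other more than either resembled parental cells. Across genes, log2 signals correlated at r = 0.9751 between the clones, with 3.82% of genes at least 2-fold apart. Against parental cells r was 0.907 for clone 1 and 0.902 for clone 2, with 14.5% and 15.1% of genes at least 2-fold apart. The differences from parental cells correlated between the clones at r = 0.870 (Spearman rho 0.774, covariance 0.751), with the same sign in 78.2% of genes, where simulated unchanged arrays sharing 1 control gave r = 0.501 (rho 0.475, covariance 0.113) and 66.6%. These are correlations across genes, which are not independent replicates, and part of the excess may come from the shared parental array, which could not be split. Lists of the clones' own sizes would overlap in 56.8 higher and 71.9 lower genes if they were independent. They are not, since both clones were compared with the same parental array, so these counts are too low a yardstick. Setting clone 1 against the other arrays in place of the parental array gave 0 limma calls and 118 genes at an unadjusted p under 0.05, and setting clone 2 apart gave 0 and 156, against 681 and 2432 for parental cells. With a clone set apart, the spread is the difference between parental cells and the other clone. Its SD was 0.92 for clone 1 and 0.94 for clone 2, against 0.47 between the clones. The 0 calls therefore largely restate the correlations above and are no separate check.

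Genes of epithelial cells fell together and a smaller set of mesenchymal genes rose. Of 32 epithelial genes detected, limma called 20 lower and 0 higher over all genes, and 25 lower and 1 higher when adjusted over the list alone. RAB25 and MAL2 are given above; CLDN7, a tight-junction claudin, fell 26.3-fold (adjusted p = 0.00536), and EPCAM, an epithelial adhesion molecule, fell 18.8-fold (adjusted p = 0.0361, up to 0.0529 over the settings tried), by 10.6-fold in clone 1 and 33.3-fold in clone 2. The brightest member under 2-fold, CD24, differed by log2 -0.12 (adjusted p = 0.852). The median of the list was -2.34 in clone 1 and -2.95 in clone 2 on the log2 scale, below all 10000 random lists of equal size and expression in each clone. With values below background set to the background floor, these medians were -2.34 and -2.66. Over the settings tried they ran from -2.58 to -1.43 in clone 1 and from -3.38 to -1.83 in clone 2.

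Of 33 mesenchymal genes on the array, 13 were detected on none, among them COL1A1, COL1A2, COL3A1, DCN and LUM. Among 20 detected mesenchymal genes, 5 rose and 0 fell over all genes, and 5 rose and 1 fell when adjusted over the list alone. Of these 20, 6 were below background in parental cells and so entered through the clones alone, and 1 was below background in both clones. VIM, which encodes the intermediate filament vimentin, rose 28-fold (log2 4.81, SE 0.29, adjusted p = 0.00460), and FSTL1, a secreted glycoprotein, rose 6.14-fold. The transcription factors ZEB2 and ZEB1, repressors of epithelial genes, were below background in parental cells and rose at least 3.53-fold and at least 2.15-fold (adjusted p = 0.0119 and 0.0314, the latter from 0.0159 to 0.0791 over the settings tried). The list medians were 0.42 in clone 1 and 0.52 in clone 2, at percentiles 99.9 and 99.99 of random lists, or 0.42 and 0.30 with values below background set to the floor. Over the settings tried they ran from 0.10 to 0.61 and from 0.14 to 1.39, and they no longer stood apart from random lists with no filter on dim probes. CALD1, the brightest member under 2-fold, differed by 0.10 on the log2 scale and by -0.0125 after median scaling.

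Lung lineage genes were lower as well. NKX2-1, the transcription factor that marks lung adenocarcinoma and alveolar cells, fell at least 23.8-fold (adjusted p = 0.00348), NAPSA, the aspartic protease napsin A, fell 26.2-fold (adjusted p = 0.0110), and ABCA3, a lipid transporter of lamellar bodies, rose 4.66-fold. Over all genes 4 of 9 detected members fell and 1 rose, and 6 fell and 1 rose when adjusted over the list alone, with medians of -1.38 and -1.74, below all random lists in both clones, or -1.37 and -1.32 with the floor. These medians depend on the filter: that of clone 1 ran from -1.51 to -0.18 over the settings tried, and that of clone 2 turned to 0.34 with probes detected on all 3 arrays. FOXA2, the brightest member under 2-fold, differed by 0.48 (adjusted p = 0.564).

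**Figure D2:**
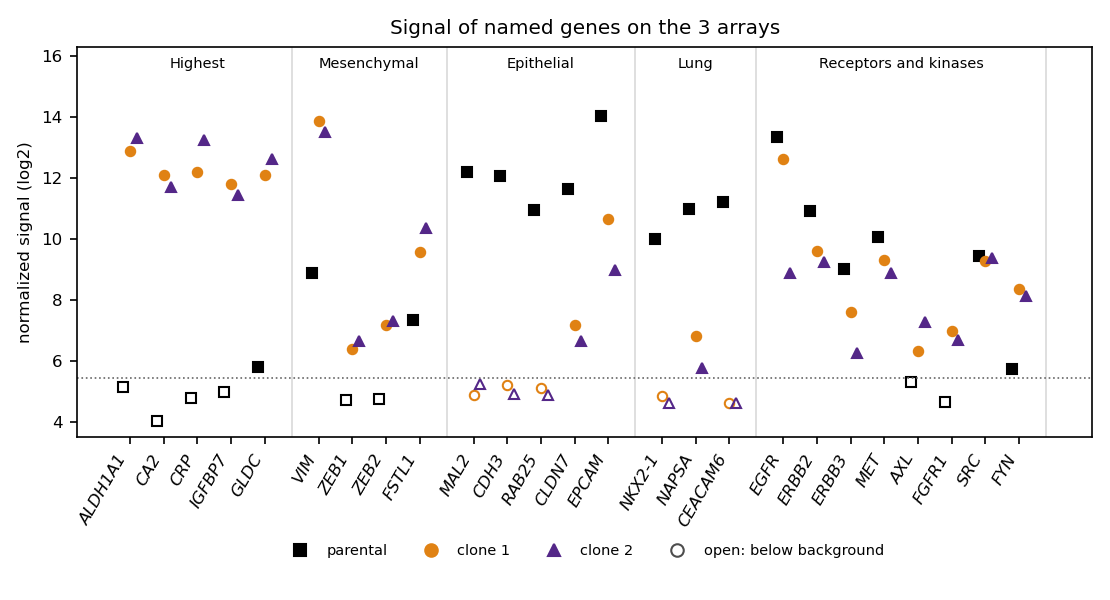
Normalized log2 signals of named genes on the parental array (squares), clone 1 (circles) and clone 2 (triangles), 1 array each; open symbols are below background and the dotted line is the mean over arrays of the lowest signal detected. VIM went from 8.89 in parental cells to 13.88 and 13.51 in the clones, and EPCAM from 14.05 to 10.64 and 8.99.

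Among receptors of the ERBB family, whose kinases the drug inhibits, EGFR differed between the clones. EGFR was 1.65-fold lower than in parental cells in clone 1 and 21.9-fold lower in clone 2, and the mean of the clones was not called by limma (log2 -2.59, SE 1.46, adjusted p = 0.399). Its dimmer probes had mean differences of -0.15 and -1.51, the former from a probe below background in clone 2. The latter probe had log2 signals of 8.60 in parental cells, 8.53 in clone 1 and 5.66 in clone 2. On that probe EGFR was thus lower in clone 2 and close to its parental level in clone 1. ERBB2 was 2.81-fold lower (adjusted p = 0.0579, from 0.0363 to 0.0719 over the settings tried). ERBB3 was 4.23-fold lower on its brightest probe (adjusted p = 0.134). The other ERBB3 probes differed by -0.0167 and -0.36, the latter below background in both clones. HBEGF, a ligand of EGFR, rose 4.82-fold (adjusted p = 0.0431), with an adjusted p of up to 0.0791 over the settings tried. Of 11 detected receptors and ligands of this family, 1 rose and 0 fell over all genes, and 1 rose and 1 fell when adjusted over the list alone, with medians of -0.17 at percentile 16.2 in clone 1 and -0.61 at percentile 0.290 in clone 2.

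Other receptor kinases moved in both directions. MET, the receptor of hepatocyte growth factor, had log2 differences of -0.76 in clone 1 and -1.16 in clone 2 and was not called (adjusted p = 0.167). AXL, a receptor kinase of the TAM family, was below background in parental cells and at least 1.85-fold higher in clone 1 and at least 3.61-fold in clone 2, and was not called either (adjusted p = 0.155). FGFR1, a fibroblast growth factor receptor, rose at least 2.63-fold (adjusted p = 0.0201, up to 0.0526 over the settings tried), and PDGFC, a ligand of platelet-derived growth factor receptors, rose 3.37-fold (adjusted p = 0.0361). MERTK, related to AXL, fell 5.62-fold (adjusted p = 0.0121), and MST1R at least 2.29-fold (adjusted p = 0.0375, up to 0.0791). In this list of 17 detected genes limma called 2 higher and 2 lower, or 5 and 6 when adjusted over the list alone, and the medians were 0.35 (percentile 98.3) and 0.59 (percentile 99.97). With no filter on dim probes those medians turned to -0.11 and -0.035, as members below background on all arrays entered.

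SRC, a target of dasatinib, was close to its parental level in both clones, at log2 differences of -0.15 and -0.0705 (adjusted p = 0.857). FYN, a kinase of the same family, rose 5.70-fold (log2 2.51, SE 0.27, adjusted p = 0.0128). Its other probes differed by 1.61, 0.82 and 1.53, each below background in parental cells. DDR1, a collagen receptor kinase, fell 4.31-fold (adjusted p = 0.0173). The other DDR1 probe differed by -0.71 and was below background in both clones. FRK and LYN were 2.42-fold and 2.23-fold lower without a call (adjusted p = 0.0742 and 0.0851), and YES1 differed by 0.0129, or by -0.0775 after median scaling. Over all genes 1 of 12 detected SRC family members and other dasatinib targets rose and 1 fell, and 1 rose and 4 fell when adjusted over the list alone. The list medians of -0.0437 and -0.0543 lay at percentiles 38.3 and 36.6.

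Of 14 detected integrins 4 fell, over all genes and also when adjusted over the list alone, and 0 rose. ITGB2, the shared beta chain of leukocyte integrins, fell 19.1-fold (adjusted p = 0.00462), ITGB4, of hemidesmosomes, 4.71-fold in clone 1 and at least 6.18-fold in clone 2, where its probe was below background (adjusted p = 0.0188), ITGA2, of a collagen receptor, 3.42-fold, and ITGB6 at least 2.08-fold (adjusted p = 0.0387, up to 0.0863 over the settings tried), while ITGB1 differed by 0.20 (adjusted p = 0.722). The integrin medians were -0.15 and -0.10 (percentiles 15.2 and 28.4). Among 17 focal adhesion adaptors 2 fell and 0 rose, or 3 and 1 when adjusted over the list alone. BCAR3 was 2.69-fold lower (adjusted p = 0.0474, up to 0.0585) and FERMT2 2.41-fold higher (adjusted p = 0.0660). NEDD9 was 2.89-fold lower (adjusted p = 0.0422, up to 0.158 over the settings tried). Its other probes differed by -0.55 and -0.46, the latter below background in both clones. CAV1, the brightest member under 2-fold, differed by 0.00303, or by -0.11 after median scaling, and the medians were 0.17 and 0.0370 (percentiles 83.4 and 53.2).

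Of 19 detected genes switched on by ERK signalling, downstream of EGFR, 4 were at least 2-fold lower in both clones and 1 was higher. Limma called 0 higher, over all genes and over the list alone. DUSP6, an ERK phosphatase, fell at least 15.2-fold in clone 1, where it was below background, and 9.49-fold in clone 2 (adjusted p = 0.0116), the 1 call among 19 detected genes, and 3 fell when adjusted over the list alone. EGR1 was 3.87-fold lower in clone 1 and 28.4-fold in clone 2 (adjusted p = 0.189), and FOS 3.75-fold lower (adjusted p = 0.0510). SPRY1 was 2.36-fold lower (limma adjusted p = 0.0876, other probe -1.18). EPHA4, an ephrin receptor below background in parental cells, was at least 2.09-fold higher (adjusted p = 0.177), but only at least 1.40-fold in clone 1. CCND1, which encodes cyclin D1, differed by 0.57 (adjusted p = 0.407). The medians were -0.21 and 0.11 at percentiles 4.81 and 71.3. TGF-beta responsive genes had 0 calls among 13, over all genes and over the list alone, with BAMBI 2.46-fold higher (adjusted p = 0.0857). PMEPA1 was 3.21-fold lower on its brightest probe (adjusted p = 0.101) and at 0.67 and -0.75 on its others, the former above background in clone 1 alone. TGFBI differed by -0.12, and the TGF-beta medians were -0.13 and -0.26 (percentiles 14.6 and 5.29). Of 22 YAP and TEAD targets 3 rose and 2 fell, or 4 and 3 when adjusted over the list alone. CCN2, a matricellular protein, rose 6.54-fold (adjusted p = 0.0168), ANKRD1 was 5.72-fold higher (adjusted p = 0.0573), NT5E, the ectonucleotidase CD73, fell 10.5-fold (adjusted p = 0.00619), and the medians were 0.0602 (percentile 62.4) and 0.62 (percentile 99.99), the latter 0.45 with the floor.

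Several genes tied to drug handling and survival changed. Among 14 aldehyde dehydrogenases, drug transporters and stem cell genes 3 rose and 2 fell, or 3 and 3 when adjusted over the list alone. ABCB1, the efflux pump P-glycoprotein, rose 7.45-fold (log2 2.90, SE 0.30, adjusted p = 0.0117), and CD44, a hyaluronan receptor, rose 3.94-fold (adjusted p = 0.0202; other probes 0.18 and 2.45). ALDH1A3 went the opposite way from ALDH1A1 and fell 47.2-fold (adjusted p = 0.0477, up to 0.0682 over the settings tried), by 114-fold in clone 1 and 19.5-fold in clone 2. The medians of this list were -0.15 and -0.29 (percentiles 14.1 and 3.83). Of 13 BCL2 family genes 1 rose and 1 fell, or 2 and 1 when adjusted over the list alone. BCL2, an inhibitor of apoptosis, rose at least 16-fold (adjusted p = 0.00460), and BMF, an activator of apoptosis, fell at least 6.14-fold in clone 1, where it was below background, and 4.79-fold in clone 2 (adjusted p = 0.0325), while BOK, another activator, was 2.37-fold higher without a call (adjusted p = 0.0668, from 0.0456 to 0.0771 over the settings tried). BCL2L1 differed by 0.34, with list medians of 0.15 and 0.30 (percentiles 78.5 and 93.8).

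The calls among NRF2 targets split, with 2 of 20 higher and 2 lower over all genes and over the list alone. HMOX1, a heme oxygenase, rose 7.08-fold (adjusted p = 0.0228) and AKR1C2 is given above, while NQO1, a quinone reductase, fell 4.05-fold (adjusted p = 0.0477, up to 0.0633 over the settings tried) and TKT, a transketolase, 2.66-fold (adjusted p = 0.0478, up to 0.0589). Medians of -0.39 and -0.36 lay at percentiles 0.110 and 0.290, so the list stood apart as lower in both clones. PRDX1, the brightest member under 2-fold, differed by 0.41. Of 14 CDK inhibitors and p53 targets 1 rose and 0 fell over all genes and over the list alone. CDKN1C, the inhibitor p57, rose 6.89-fold (adjusted p = 0.0106), TNFRSF10B differed by 0.46, and the medians were -0.15 and -0.14 (percentiles 13.6 and 17.4). Stress and unfolded protein response genes had 0 calls among 21 over all genes and over the list alone, with ASNS 2.58-fold lower (adjusted p = 0.0973, other probe -0.65), HSPB1 at -0.32, and medians of 0.0118 and -0.20 (percentiles 40.6 and 5.49).

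None of 33 detected cell cycle genes was called over all genes or over the list alone, and 1 of them, BIRC5, which encodes survivin, was at least 2-fold higher in both clones (2.84-fold, adjusted p = 0.121, other probe 0.74). CDC20, the brightest member under 2-fold, differed by 0.12. The list medians were 0.18 in clone 1 (percentile 90) and 0.58 in clone 2, above all 10000 random lists. Sterol synthesis genes had 1 call among 18, over all genes and over the list alone. INSIG1, a sterol-sensing regulator, fell 5.64-fold (adjusted p = 0.0407, up to 0.0562 over the settings tried), SCD was 2.58-fold lower (adjusted p = 0.174), and the medians of -0.38 and -0.67 lay at percentiles 0.420 and 0. Of 25 glycolysis and hypoxia genes 1 fell and 0 rose, over all genes and over the list alone. EGLN3, an oxygen-sensing hydroxylase, fell 5.61-fold (adjusted p = 0.0143), while HK1 and PGAM1 were 2.10-fold and 2.22-fold higher (adjusted p = 0.0987 and 0.0844) and ENO1 differed by 0.28. The glycolysis medians were 0.48, above all random lists, in clone 1 and 0.21 in clone 2 (percentile 94.8). Housekeeping genes had 0 calls among 15 over all genes and over the list alone, medians of 0.11 and 0.0820 (percentiles 72.5 and 67.2), and EEF1A1 at 0.13, or -0.00349 with the mean of its probes.

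Interferon response genes had lower values in both clones, farther below parental cells in clone 1. Of 29 detected interferon response genes, 11 were at least 2-fold lower in both clones, limma called 3 lower and 0 higher over all genes, and 8 lower when adjusted over the list alone. IFI27 fell at least 17.9-fold in clone 1 and 9.63-fold in clone 2 (adjusted p = 0.0229), and OAS1, a sensor of double-stranded RNA, at least 6.70-fold and 4.36-fold (adjusted p = 0.0379), both below background in clone 1. MX2 fell at least 2.98-fold (adjusted p = 0.0155), and IFITM1 was 5.37-fold lower without a call (adjusted p = 0.0685). The medians were -1.67 in clone 1 and -0.55 in clone 2, below all random lists in each, and IFITM3, the brightest member under 2-fold, differed by -0.93 in clone 1 and 0.00180 in clone 2. Of 10 MHC genes none was called over all genes and 2 fell when adjusted over the list alone, with HLA-DMA 2.75-fold lower (adjusted p = 0.0631), B2M at -0.11, and medians of -0.50 and -0.36 (percentiles 1.02 and 5.43), or -0.19 and -0.11 with the floor. Among 20 NF-kB cytokine genes 1 rose and 1 fell, or 2 and 2 when adjusted over the list alone. IL1B, a proinflammatory cytokine, fell 7.18-fold in clone 1 and at least 7.68-fold in clone 2, where it was below background (adjusted p = 0.00939), SOD2, a mitochondrial superoxide dismutase, rose 4.01-fold (adjusted p = 0.0340), NFKBIA differed by 0.21, and the medians were 0.0588 (percentile 65.7) and 0.44 (percentile 99.9).

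Of 14 leukocyte markers on the array 9 were detected in some of the cells, 3 fell over all genes and over the list alone, and 0 rose. CSF1R fell at least 2.34-fold (adjusted p = 0.0201, up to 0.0522 over the settings tried), LCP1, an actin-bundling protein, 3.27-fold (adjusted p = 0.0308), and CD14 2.94-fold (adjusted p = 0.0431, up to 0.0658), while CD68 differed by 0.13. Leukocyte medians were -0.22 and -0.48 (percentiles 17.9 and 3.12), or -0.0511 and -0.30 with the floor. Endothelial markers had 4 of 11 detected and 0 calls over all genes and over the list alone, with ENG at -0.42 and medians of -0.13 and -0.0189 (percentiles 30.5 and 48.2). In the squamous and basal list 1 of 8 genes rose and 1 fell, or 1 and 3 when adjusted over the list alone. The desmosomal cadherin DSC3 rose 4.84-fold (adjusted p = 0.0156), SERPINB5 fell at least 2.26-fold (adjusted p = 0.0429, up to 0.0876), KRT15 was 2.85-fold lower (adjusted p = 0.204), and the medians of -0.55 and -0.57 lay at percentiles 1.54 and 2.12, or -0.31 and -0.26 with the floor, turning to 0.063 and 0.052 with no filter on dim probes. Neuroendocrine genes gave 1 rise and 1 fall among 7, or 2 and 2 when adjusted over the list alone. The adhesion molecule NCAM1 rose at least 9.03-fold on its brighter probe (adjusted p = 0.0368, up to 0.0791 over the settings tried). Its other probe differed by 0.77 and was below background in parental cells. SYT1 fell 3.28-fold (adjusted p = 0.0366, up to 0.0557), DDC differed by -0.90, and the neuroendocrine medians were -0.0128 and 0.32 (percentiles 46.9 and 90.4).

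**Figure D3:**
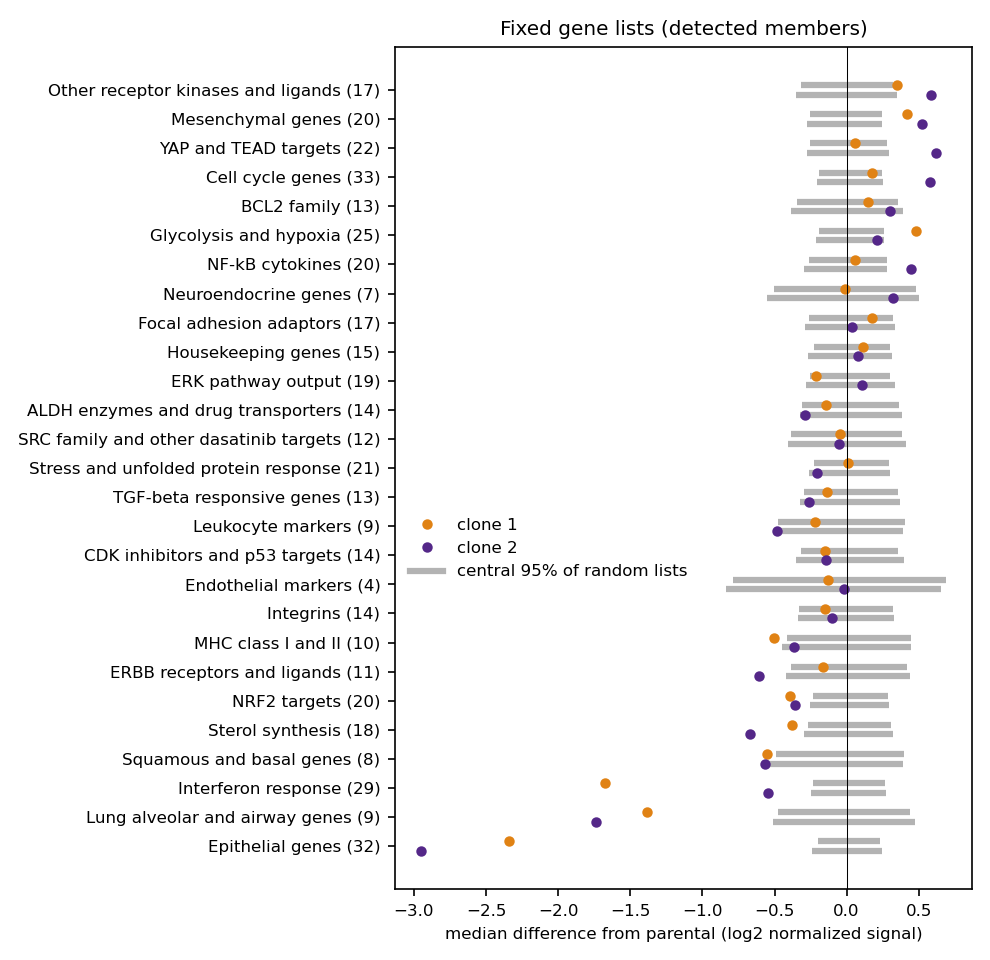
Median log2 difference from parental cells of each gene list in clone 1 (orange) and clone 2 (purple), with the number of detected members in parentheses; grey bars span the central 95% of 10000 random lists matched on expression. The epithelial list lies farthest below its bars, at -2.34 and -2.95. The lung, interferon, NRF2, sterol and squamous lists also lie below theirs in both clones. The mesenchymal list and that of other receptor kinases lie above their bars in both clones.

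Taken singly, clone 1 had 828 genes at least 2-fold higher and 870 at least 2-fold lower than parental cells, and clone 2 had 806 and 971. With 1 array on each side, these counts and the comparison of the clones have no replicate check and no test.

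Set against each other, the clones differed most in a few genes that 1 of them had kept or gained. IL13RA2, a decoy receptor of interleukin 13, was 62.9-fold higher in clone 2, OLR1, a scavenger receptor, at least 26.8-fold higher, TMEM52B at least 22.1-fold, PRSS3, a trypsin, at least 12-fold, TMEM98 at least 9.84-fold, and BST2, the antiviral protein tetherin, 12.5-fold. PRSS3 and BST2 were within 1.16-fold of parental cells in clone 2 and in clone 1 at least 10.3-fold and 14-fold lower. In the other direction, FST, which encodes the activin antagonist follistatin, was 14.6-fold lower in clone 2 than in clone 1, VOPP1 13.4-fold, EGFR 13.3-fold, PNCK, a calmodulin-dependent kinase, 12.4-fold, GSTA1, a glutathione transferase with near-identical relatives, 9.33-fold, and VGF, a neuropeptide precursor, 8.40-fold. Altogether 216 genes were at least 2-fold higher in clone 2 than in clone 1 and 233 at least 2-fold lower.

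By list, 15 of 29 interferon genes were at least 2-fold higher in clone 2 than in clone 1 and 0 lower, among them BST2 and IFI44, 5.81-fold higher. The median difference of the interferon list was 1.13, above all random lists, or 0.91 with values below background set to the floor. NF-kB cytokine genes had 5 members higher in clone 2, among them CCL2, at least 2.52-fold, and CXCL5, 2.74-fold, with a median of 0.54 above all random lists. Cell cycle genes were higher in clone 2 by a median of 0.42, also above all random lists, with 0 members at least 2-fold apart. LOX, a collagen-crosslinking enzyme, was at least 3.79-fold higher in clone 2, and NRG1, a ligand of ERBB3, 2.65-fold. ERK output genes had a median of 0.31 (percentile 99.8), with EGR1 7.35-fold lower in clone 2 and EPHA4 2.23-fold higher. TGF-beta, YAP and mesenchymal genes also stood apart as higher in clone 2, at 0.33, 0.30 and 0.19 (percentiles 99.8, 99.9 and 98.1), but with the floor the TGF-beta median was 0.22 and the mesenchymal 0.15, both within the range of random lists drawn without the floor. Lower in clone 2 were sterol genes at -0.33 (percentile 0.0400), stress genes at -0.28 (percentile 0.130), glycolysis genes at -0.22 (percentile 0.305) and epithelial genes at -0.27 (percentile 0.0900), the last 0.0259 with the floor. KRT19, a keratin, was 5.34-fold lower in clone 2 than in clone 1.

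Genes that follow EGFR on chromosome 7 were also lower in clone 2 than in clone 1, a comparison chosen after EGFR and VOPP1 had been seen together in the list of largest differences. In clone 2 LANCL2 was 8.69-fold lower than in parental cells, VOPP1 13.5-fold, MRPS17 4.14-fold, NIPSNAP2 3.93-fold, PSPH 4.37-fold and SUMF2 3.85-fold, while in clone 1 each of them lay within 1.36-fold of parental cells. In the same stretch CCT6A was 1.86-fold lower in clone 2, and ZNF713 had a log2 difference of -0.58. On the other side of EGFR, COBL and SEC61G-DT differed between the clones by -0.45 and -0.48. A scan of neighbouring genes, run after these values had been seen, also found a stretch of chromosome 17 that was higher in both clones. From AATF to SOCS7, 8 of 9 detected genes were at least 2-fold higher in each clone, with ACACA, the acetyl-CoA carboxylase of fatty acid synthesis, 4.95-fold higher in clone 1 and 6.35-fold in clone 2, TADA2A 10.9-fold and 20.1-fold, DUSP14, a phosphatase, 13.7-fold and 23.8-fold, and MRPL45 7.98-fold and 9.64-fold. TBC1D3C, a member of a multicopy family near background, was the exception at 1.10-fold and 1.09-fold. It was above background in clone 1 alone, so these values cannot show that it was unchanged.

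**Figure D4:**
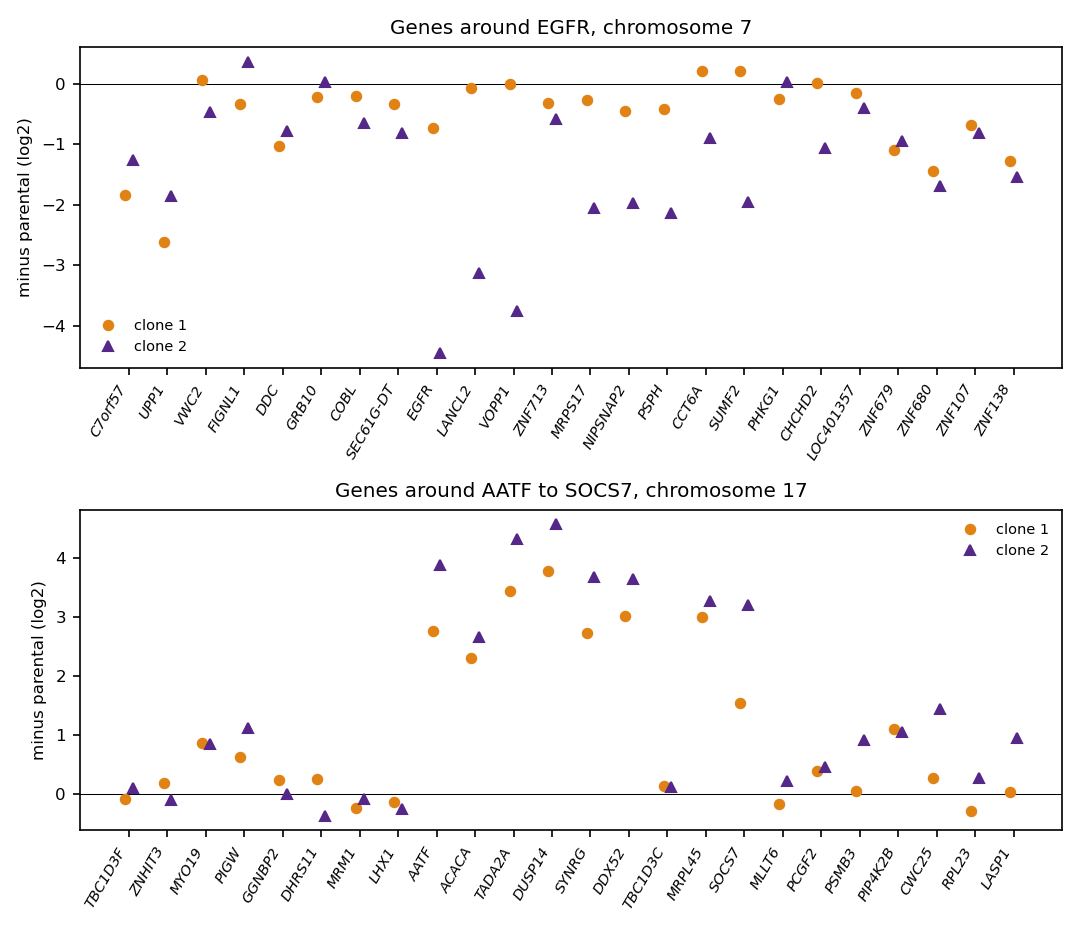
Log2 differences from parental cells in clone 1 (circles) and clone 2 (triangles) of genes in chromosomal order, evenly spaced and not to genomic scale, around EGFR (top) and around AATF to SOCS7 (bottom). EGFR stands at -0.72 in clone 1 and -4.45 in clone 2, and AATF at 2.77 and 3.88.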

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

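The probes and genes below were picked by fixed kinds of signal after the values had been computed, and the differences between the clones were not tested. Among 20692 probes with no listed gene, outside the comparisons of named genes, 3287 exceeded background on some array, and 91 of these were at least 2-fold higher in both clones than in parental cells and 115 at least 2-fold lower. PNCK differed from parental cells in opposite directions in the clones, 4.01-fold higher than parental cells in clone 1 and 3.08-fold lower in clone 2, a log2 difference of -3.63 for clone 2 minus clone 1. LOX was at least 1.52-fold lower than parental cells in clone 1, where it was below background, and 2.49-fold higher in clone 2, a measured log2 difference of 2.75 between the clones that counts, against the background floor, as at least 3.79-fold.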

How the results depend on the processing

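The offset of 50, the receptor-family filter and the test against 2-fold were chosen after seeing the data; the other settings were planned. The limma total of 681 genes ranged from 538 to 858 over the normalizations, probe rules and the other filters. It came to 271 (144 higher, 127 lower) among 9702 genes whose probes were detected on all 3 arrays, which leaves out genes silent on one side, and to 198 (87 higher, 111 lower) when tested against 2-fold, a stricter question. With the former filter 367 genes were 2-fold lower in both clones, 560 lower in clone 1, 641 lower in clone 2 and 141 higher in clone 2 than in clone 1. An offset of 50 left 136 genes higher and 141 lower in clone 2 than in clone 1, by shrinking differences of dim probes. The 1.5-fold and 3-fold rules, which differ by construction, gave 1240 and 271 genes higher and 1325 and 319 lower in both clones, 1826 and 380 higher and 1861 and 426 lower in clone 1, 1904 and 369 higher and 2005 and 434 lower in clone 2, and 818 and 57 higher and 936 and 52 lower in clone 2 than in clone 1. Agreement between the clones was r = 0.839 with probes detected on all 3 arrays, 0.851 with no filter and 0.878 with the receptor-family filter, against 0.870; the cause was not tested. Without resistant replicate 1 or 2, the size rule counted 806 to 828 genes higher and 870 to 971 lower in the clone left, and limma had no residual degrees of freedom.

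Setting a clone apart in place of parental cells gave 0 calls in the 8 alternatives run, which leave out the trend and the test against 2-fold. Those 0 calls largely follow from the distance of parental cells from the clones and are no separate check. Direction turned in 7 list medians that had stood apart from random lists, and in 26 other cases for medians inside their range, such as those of the SRC family, ERK output and housekeeping lists. With no filter, other receptor kinases came to -0.11 in clone 1, -0.035 in clone 2 and -0.071 for their mean, and squamous genes to 0.063, 0.052 and 0.021, with undetected members entering. With probes detected on all 3 arrays the lung list came to 0.34 in clone 2. In clone 1 the lung and MHC medians, and in both clones the mesenchymal and squamous medians, no longer stood apart from random lists under at least 1 filter. Of 72 named genes called, 55 kept the call under each of the 8 normalization, probe and filter settings that held them and 17 lost it under at least 1, with no reversal (the trend and the test against 2-fold were not followed gene by gene): ALDH1A3, BCAR3, CD14, CSF1R, EPCAM, FGFR1, HBEGF, INSIG1, ITGB6, MST1R, NCAM1, NEDD9, NQO1, SERPINB5, SYT1, TKT and ZEB1. A further 9 gained a call under at least 1 of the 8: ANKRD1, BOK, ENO2, ERBB2, FERMT2, FOS, HLA-DMA, IFITM1 and PGAM1. Of the 72, the filter on all 3 arrays held 35, of which 26 kept the call, and the rest of the 72 were not exposed to that filter. Probes at background limit the sizes of 179 of the 557 higher and 191 of the 628 lower genes. The chip as a block was not run. No paired analysis was possible because the groups share fewer than 2 replicate numbers.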

Other observations

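Other runs of neighbouring genes also differed between the clones, in a scan chosen after the data were seen. On chromosome 14 the interferon regulator IRF9 and its neighbours PSME1, PSME2 and RNF31 were higher in clone 2 than in clone 1, with a running median of 1.37 that 1 of 1000 shuffles of the gene order reached. On the X chromosome a run that includes IL1RAPL1 was higher in clone 1 than in parental cells, with a running median of 2.64 reached in 10 shuffles, and lower in clone 2 than in clone 1, at -1.36, reached in 2. A run around SPIRE2 on chromosome 16 was lower in clone 2 at -1.13, reached in 16 shuffles, and a run of glutathione transferases around GSTA5 on chromosome 6 at -1.09, reached in 25. Runs around STXBP6 on chromosome 14 (1.08, 30 shuffles) and BEX1 on the X chromosome (1.06, 34 shuffles) were higher in clone 2 than in clone 1. Against parental cells, a run on chromosome 18 that includes BCL2 and SERPINB3 was higher in clone 2 (2.61, 20 shuffles), although SERPINB5 at its centre fell. A run around IL1RAP on chromosome 3 was also higher in clone 2 (2.26, 45 shuffles). The run on chromosome 6 holds near-identical genes, whose probes cannot all be told apart, and GSTA1 itself was at least 17.8-fold higher than parental cells in clone 1 and at least 1.91-fold in clone 2.

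Of the tests below, the one on fibroblast genes was fixed before its result was seen, and the others were chosen after the patterns had been seen. The first pattern is the lower EGFR region in clone 2. In a scan of all chromosomes with windows of 7 genes, the lowest window that holds EGFR had a median of -1.79 (log2 clone 2 minus clone 1), and 0 of 1000 shuffles of the gene order gave a window as far from 0, which argues against a change of EGFR or its probe alone. The difference of EGFR was -3.67 in raw signals scaled only to a common median, which argues against array normalization. The 6 genes before EGFR and the 6 after SUMF2 had medians of -0.098 and -0.18, but the ends of the run were placed by its values, and CHCHD2 beyond them was still 2.11-fold lower in clone 2. Fewer copies of the region and a regional loss of transcription therefore cannot be told apart, as DNA was not measured.

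The second pattern is the run from AATF to SOCS7, with medians of 2.77 in clone 1 and 3.66 in clone 2. Shuffling the gene order gave a window as high in 2 of 1000 shuffles for clone 1 and in 0 of 1000 for clone 2, which argues against changed genes lying together by chance, and in raw signals scaled only to a common median the smaller of the clones' medians was still 2.64, which argues against normalization. The medians of the 6 genes on either side reached at most 0.69, but the ends of this run too were placed by its values. More copies of the region in both clones and a shared change of transcription cannot be told apart, as DNA was not measured, and the labels do not say whether the clones arose from separate cells.

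The third pattern is the lower epithelial and lung genes with higher VIM in both clones. Of 5 abundant fibroblast genes, COL1A1, COL1A2, COL3A1, DCN and LUM, 0 were above background in both clones, which argues against fibroblasts mixed into the cultures; other cell types were covered by the leukocyte and endothelial lists alone. The epithelial median nearest to 0 was -2.17 in raw signals scaled only to a common median, which argues against normalization. Between the clones r was 0.9751 and 3.82% of genes were at least 2-fold apart, against 14.5% and 15.1% from parental cells. That argues against another cell line in place of 1 clone alone. Another line in place of both clones cannot be told apart from a change of state, as no genotype was measured. EGFR, LANCL2 and VOPP1 were picked because they differed most between the clones. Their median difference from parental cells was -0.071 in clone 1 and -3.75 in clone 2, which does not settle the question. A shift from an epithelial toward a mesenchymal state during selection, which the design names only as resistance, remains a hypothesis.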
